A study of Rattus norvegicus with 8 samples.

How the data were processed

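The series holds 8 RNA libraries from the lower spinal cord of Sprague Dawley rats, an outbred laboratory strain, collected 23 days after a spinal cord injury. Per the labels, 4 libraries came from rats that were trained after the injury and 4 from rats that were not, and the groups are called trained and untrained here. The series' design text places the hemisection at T9 and describes the sampled lower cord as intact. The kind of training and the number of animals behind each library are not given in the sources used here. P-values therefore measure the spread between these libraries, which would be technical if libraries shared an animal.

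Per the labels' protocols, the cords were flash frozen and the libraries were made by CEL-Seq2 and sequenced on an Illumina HiSeq1500. CEL-Seq2 is a 3′-end RNA-sequencing method that tags each captured transcript with a short random barcode, the unique molecular identifier (UMI), so that PCR copies of one molecule are counted once. The submitters' processing notes name HISAT2 2.0.4, an aligner, HTSeq 0.6.0, a read counter, and the rat genome build Rnor_6.0. The length of the UMI, the step that collapsed reads to UMIs and any correction of UMI errors are not given in the sources used here. The authors deposited one table of raw counts, the UMI counts of 32883 Ensembl genes in the 8 libraries, without normalisation. The values were whole numbers, every row had a gene identifier, and the column names held the same letter and number as the sample titles. The titles and columns of all 8 libraries also carried the tag L2, whose meaning the labels do not give.

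The deposited table names genes by Ensembl identifier alone. None of the 32883 identifiers matched an entry of the RefSeq gene table at hand (assembly GRCr8), whose field for Ensembl identifiers is empty. Gene symbols and positions were therefore not used here. The 43 lists of cell type markers and pathway genes that had been fixed in advance could not be tested for the same reason. Of the genes, at most 2 higher and 2 lower in trained libraries are printed by identifier. The rule fixed beforehand covered the case of fewer than 20 genes past the threshold, and named those with a mean of at least 5 CPM (counts scaled to a common library total) and the smallest unadjusted p in each direction. The first 2 of each direction were kept.

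Counts were analysed in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 (a minimum count of 10 in a library of median size, in at least 4 libraries), which left 4086 genes. Library sizes were scaled by the trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood F test of trained minus untrained over all 8 libraries, with no covariate and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors were the fold change divided by the square root of F, and intervals are 95% intervals from the same fit. CPM values of genes use TMM-scaled library sizes summed over the 4086 genes kept, and log2 CPM values add a prior count of 2. Single library measures were compared by two-sided exact permutation tests over the 70 ways to assign 4 of 8 libraries, with Benjamini-Hochberg adjustment over the 4 measures tested.

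The sample titles number the libraries 1 to 4 in each group, and the labels do not say what a number stands for. It was therefore checked whether libraries with the same number deviated together from their group means. The criterion was a correlation over 0.1 in every pair. It used no call of either fit, but the count of calls with the block was seen together with the correlations. Across the 4086 genes, which are not independent replicates, the correlation of these deviations lay between 0.30 and 0.53 for the 4 same-numbered pairs, with a mean of 0.38. The labelled pairing had the highest mean of all 24 possible pairings (the next had 0.33; one-sided exact permutation p = 0.0417, the smallest these pairings can give). All 8 libraries correlated best with the library of their own number. The criterion alone did not single out the labelled pairing. The next pairing, which exchanged numbers 1 and 2, also passed. Its exchanged pairs had 0.27 and 0.23, against 0.34 and 0.34 in the labelled ones. Exchanging numbers 3 and 4 did not pass (0.0089 and 0.057). For numbers 1 and 2 the pairing therefore rests on the higher correlations of the labelled pairs, not on the criterion. The numbers were taken to pair the libraries on this evidence from the data, and the fit with the replicate number as a block is given beside the fit without it.

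Replicates were compared before averaging. A chi-square test of the counts of 2 libraries of one group, over genes with at least 20 UMIs in the pair, gave 2.83 to 5.61 times its degrees of freedom in the 12 pairs, so no pair looked like one library deposited as 2 samples. The totals ran from 192472 to 453390 UMIs per library. A count of 0 allowed a level of up to 6.62 CPM in the deepest and 15.6 CPM in the shallowest library (3 counts of the unscaled total over all genes). The CPM values of genes are on another scale, on which 3 UMIs in the shallowest library were 18.4 CPM. These limits cover counting error only.

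The models were tested on simulated data: 10 simulated data sets of 4086 genes at the observed levels, depths and dispersions, each with 100 genes changed 2-fold and 100 changed 4-fold. The fit without the block recovered 47.7% of the 2-fold and 87.8% of the 4-fold changes in the trained against untrained comparison, with on average 5.80 false calls. The blocked fit recovered 72.3% and 88.2% of these changes, with on average 5.20 false calls. Both simulations took dispersions from the trend over abundance and drew genes independently. The simulation without the block gave same-numbered libraries no shared deviation, unlike the real libraries. Its recovery rates therefore do not give the power of that fit on these data. Alternatives fixed before the data were examined were other scalings (the median-ratio factors of DESeq2, upper quartile), other filters, the DESeq2 1.42.0 Wald test, voom from limma 3.58.1 with and without quality weights, robust edgeR fits, a threshold of 0.10, the replicate block and the removal of each library. Added after seeing the data were a correction for chance re-use of UMIs, a term for libraries numbered 1 and 2 against 3 and 4, fits within each of these sets, a filter of 20 UMIs in 4 libraries the removal of each pair and the combinations of these choices with the block. The correction replaced a count n by K × ln(K / (K − n)), rounded, on the assumption of a 6-base UMI with K = 4096 different sequences.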

Results

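Gene expression was measured in the lower spinal cord of rats 23 days after a hemisection at T9, in 4 libraries from trained and 4 from untrained animals. The 8 libraries held 2466500 UMIs in all. Untrained libraries held 384167, 365523, 240895 and 453390 UMIs for replicates 1 to 4, and trained libraries held 400934, 216786, 192472 and 212328. The mean total was 360994 ± 88541 UMIs in untrained and 255630 ± 97444 in trained libraries (SD, n = 4 each), a difference within the spread between libraries (two-sided exact permutation test, p = 0.171, adjusted p = 0.305). Between 8727 and 10623 genes had at least 1 UMI in a library, and 13048 of the 32883 genes in the table had one in any library. The 4086 genes with enough counts for a test are the basis of what follows.

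The study asked how training after a spinal cord injury affects the transcriptome of the uninjured cord below it. No gene passed the test of a difference between trained and untrained cords in the comparison of all 4 libraries against 4 (edgeR quasi-likelihood test, 0 of 4086 genes past an adjusted p of 0.05, smallest adjusted p = 0.99998). When libraries with the same replicate number were compared as pairs, 2 genes passed the threshold, both higher in trained cords (edgeR with the replicate number as a block). These were ENSRNOG00000029042, 5.68-fold higher with most of the difference in replicates 1 and 4, and ENSRNOG00000062158, 2.21-fold higher. Of the 8 ways to exchange trained and untrained within pairs, 5 gave at least 2 genes, the real labels included. Both calls were lost with the block in DESeq2, which ran without the filter on 13048 genes (0 genes), and in edgeR without replicate 1 (0 genes). That of ENSRNOG00000062158 was also lost with median-ratio scaling, a robust fit or corrected counts (edgeR adjusted p of 0.0515, 0.0720 and 0.128). Looser filters with the block, chosen after seeing the data, gave more genes in edgeR, 5 with 5 CPM in 4 libraries and 18 with no filter. Leaving out replicate 3 or replicate 4 gave 5 genes each over the same 4086. Over all genes tested, the fold changes were small, with a median absolute log2 fold change of 0.15.

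At an unadjusted p under 0.05, the edgeR fit without the block gave 52 genes, of which 30 were higher and 22 lower in trained libraries, where 204.3 would be expected by chance. DESeq2, over the 13046 genes to which it gave an adjusted p, gave 63 such genes and limma-voom 57, and neither gave a gene past its adjusted threshold. With the block, edgeR gave 171 genes at an unadjusted p under 0.05, limma-voom 194 and DESeq2 35. The edgeR and limma-voom counts with the block also lay below the 204.3 expected by chance. That number does not apply to DESeq2, which ran over more genes. The 2 genes called by edgeR with the block were also the 2 called by limma-voom with the block, whereas DESeq2 with the block called 0. The 4 trained libraries all lay above the 4 untrained ones for 20 genes and all below for 25, together 1.10% of the genes, against 2.86% by chance. This share and, for the fits without the block, the 204.3 genes assume 8 exchangeable libraries, whereas same-numbered libraries deviated together. All 4 pairs changed in the same direction for 490 genes, or 11.99%, against 12.5% by chance.

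The precision of these data gives an approximate bound on the change of a gene that could have been missed. The intervals are for single genes, without adjustment over the genes tested. They can be narrower than the p of the same test implies. Without the block, the 95% interval of the log2 fold change had a median half-width of 0.62, and for 3268 genes (80.0%) the interval excluded a 2-fold change in either direction. With the block the median half-width was 0.49 and 3654 genes (89.4%) excluded a 2-fold change. For the remaining genes a change of 2-fold was not excluded at this depth. The biological coefficient of variation between libraries was 23.1% without the block and 12.5% once the replicate number was in the model.

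ENSRNOG00000029042 stood at 32.6 ± 19.98 CPM in untrained and 187 ± 191 CPM in trained libraries (SD, n = 4 each). Its log2 fold change was 2.47 ± 0.66 (SE, edgeR adjusted p = 0.99998) without the block and 2.51 ± 0.29 (adjusted p = 0.000225) with it. The difference came mainly from replicates 1 and 4, where 119 and 74 UMIs in trained libraries faced 15 and 26 in untrained ones. In replicate 2 the trained library had 3 UMIs and the untrained one 5, and in replicate 3 they had 6 and 4. Trained libraries were higher in all 4 pairs, by 2.73, 0.08, 0.75 and 2.65 on the log2 scale for replicates 1 to 4. The blocked estimate of 2.51 lay near those of replicates 1 and 4, which held most of the counts, and above those of replicates 2 and 3. Its SE of 0.29 does not show how unequal these 4 differences were. Without replicate 1, over the same 4086 genes, its log2 fold change was 2.22 ± 0.40 with an edgeR adjusted p of 0.264, so the call was lost. Without replicate 4 it passed at a similar log2 fold change, 2.24 ± 0.38 (edgeR adjusted p = 0.000214), and it also passed without replicate 2 or 3. Why the call was lost without replicate 1 was not tested. These refits with a pair left out were chosen after seeing the data.

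ENSRNOG00000062158, among the most abundant transcripts of the table, stood at 2937 ± 766 CPM in untrained and 6846 ± 3373 CPM in trained libraries (SD, n = 4 each). Its log2 fold change was 1.22 ± 0.31 (SE, edgeR adjusted p = 0.99998) without the block and 1.14 ± 0.21 (adjusted p = 0.0492) with it. The 4 trained libraries, between 4003 and 11532 CPM, all lay above the 4 untrained ones, between 2003 and 3714 CPM. Its pairwise differences were 1.81, 0.60, 1.63 and 0.51 on the log2 scale. The blocked call ended without replicate 1, 2 or 3, with edgeR adjusted p of 0.669, 0.133 and 0.119 over the same genes (0.0261 without replicate 3 when the genes were filtered anew), while the log2 fold change stayed between 0.91 and 1.35 whichever replicate was left out. Its counts ran from 765 to 2794 UMIs, and the genes of its abundance class, with a mean of 500 to 1500 UMIs, had a median slope of log2 count on log2 library total of 0.94. Its counts in untrained replicate 4 (1524 UMIs) and trained replicates 1 (2794 UMIs) and 3 (1882 UMIs) lay in the range of the class of 1500 to 3000 UMIs, whose median slope was 0.48.

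The 2 genes with the smallest p without the block among those lower in trained libraries did not pass the threshold in either fit. ENSRNOG00000042905 had 163 ± 70.1 CPM in untrained and 72.7 ± 2.30 CPM in trained libraries (SD, n = 4 each), a log2 fold change of -1.15 ± 0.34 (SE) with an edgeR adjusted p of 0.99998 without the block and 0.207 with it. It was lower in 3 of 4 pairs, and replicate 2 went the other way with 59.7 CPM untrained and 72.0 CPM trained. Leaving out untrained replicate 2 brought it past the threshold without the block, at a log2 fold change of -1.43 and an edgeR adjusted p of 0.0466 (0.0466 to 0.999998 over all alternatives without the block). In edgeR fits with the block, chosen after seeing the data, it passed without replicate 2 (adjusted p = 0.00614), with no filter (0.000503) and with a filter of 5 CPM in 4 libraries (0.0407). Over all alternatives with the block, its adjusted p ran from 0.000503 (edgeR, no filter) to 0.9998 (DESeq2). ENSRNOG00000052506 had 47.3 ± 9.69 CPM in untrained and 20.1 ± 11.1 CPM in trained libraries, a log2 fold change of -1.25 ± 0.40 (SE) with an edgeR adjusted p of 0.99998 without and 0.649 with the block. It was lower in all 4 pairs, on counts of 2 to 7 UMIs in trained and 11 to 21 in untrained libraries.

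**Figure D1:**
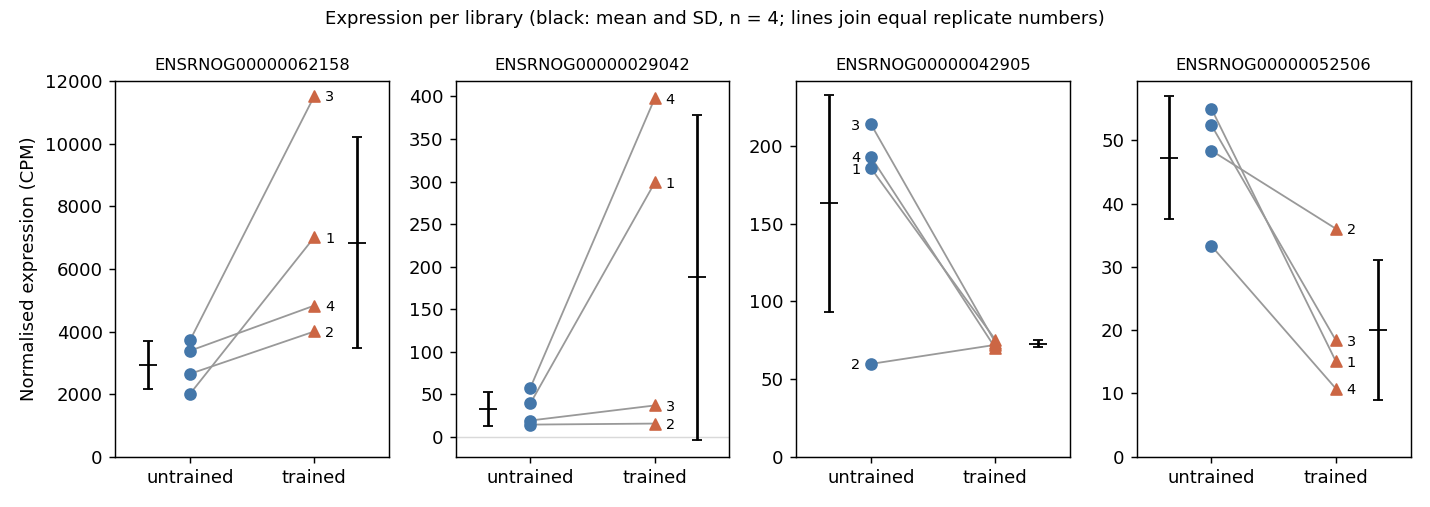
Normalised expression (CPM, vertical axis) in untrained (circles) and trained (triangles) libraries. Shown are the 2 genes with the smallest p without the block in each direction. Grey lines join libraries of equal replicate number, and black bars give the mean and SD (n = 4). In trained libraries ENSRNOG00000029042 stood at 299 and 398 CPM in replicates 1 and 4 and at 15.4 and 36.8 CPM in replicates 2 and 3, whereas the 4 trained values of ENSRNOG00000062158 all lay above the untrained ones.

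More genes differed by replicate number than by training. The first principal component of the log2 CPM values held 32.9% of the variance and placed replicates 1 and 2 of both groups between -16.5 and -12.8 and replicates 3 and 4 of both groups between 8.63 and 22.6. The second component, with 20.7%, parted replicate 3 (13.1 untrained, 23.2 trained) from replicate 4 (-9.93 and -15.5). The third, with 12.6%, placed the libraries numbered 3 at opposite ends (20.95 untrained, -14.2 trained). A comparison of the 4 libraries numbered 1 and 2 with the 4 numbered 3 and 4, chosen after these components were seen, gave 484 genes past an adjusted p of 0.05 in edgeR, 280 of them higher and 204 lower in replicates 3 and 4, while the other ways to part the numbers 2 against 2 gave 0 genes (222 and 252 at an unadjusted p under 0.05). With training as a term in that model 415 genes passed. With 1 library left out 265 to 476 genes passed, with 321, 288 and 291 without untrained replicates 1, 2 and 4 and 276, 304 and 265 without trained replicates 1, 2 and 4. Within replicates 1 and 2 alone (2 trained against 2 untrained libraries) and within replicates 3 and 4 alone, 0 genes passed in the edgeR test of training (116 and 64 at an unadjusted p under 0.05). A model of training with a term for these sets also gave 0 genes in edgeR (102 at an unadjusted p under 0.05).

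**Figure D2:**
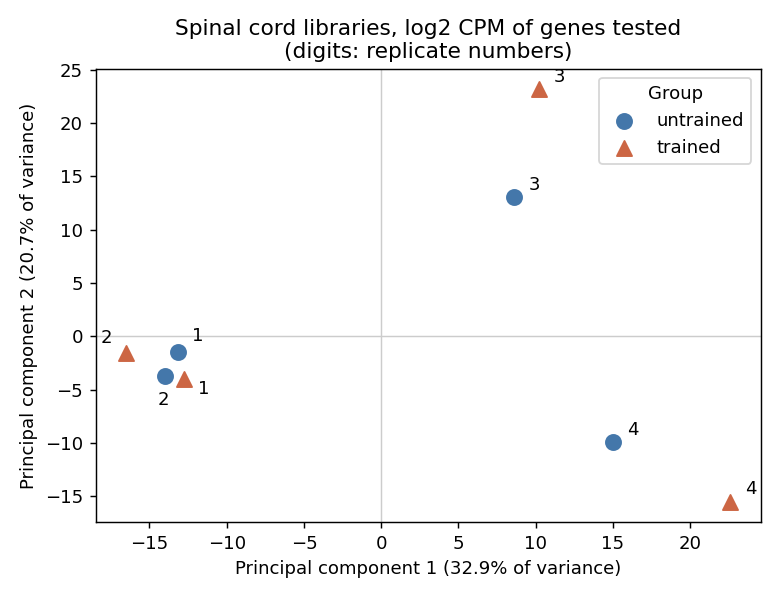
Principal components 1 and 2 (axes, arbitrary units, with their share of the variance) of the log2 CPM values of 4086 genes in the untrained (circles) and trained (triangles) libraries, each labelled with its replicate number. Replicates 1 and 2 of both groups lay together on the left, and replicates 3 and 4 of both groups lay on the right.

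The highest counts had an upper limit. The largest count of a gene lay between 3764 and 4049 UMIs in each of the 8 libraries although the totals differed 2.36-fold, and no count exceeded 4096, the number of different 6-base UMIs. The 5 genes with a mean of 3000 UMIs or more, which held 5.99% of all UMIs, hardly followed the library total, with a median slope of log2 count on log2 total of 0.07. The slope was 0.48 for the 9 genes with a mean of 1500 to 3000, 0.94 for the 55 genes of 500 to 1500 and 1.13 for the 492 genes of 100 to 500 UMIs. The 10 most abundant genes took 7.98% of the UMIs in the deepest library and 15.03% in the shallowest. Their share was 9.58% ± 2.34 in untrained and 12.5% ± 2.98 in trained libraries (SD, n = 4 each; two-sided exact permutation test, p = 0.229, adjusted p = 0.305). Counts corrected for this limit, on the assumption of a 6-base UMI, also gave 0 genes in edgeR without the block (53 at an unadjusted p under 0.05), and 1 gene with it.

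**Figure D3:**
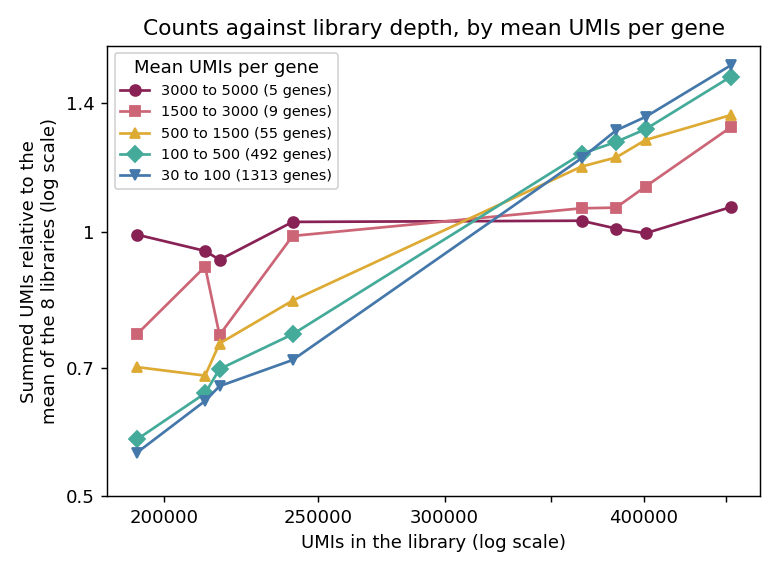
Summed UMIs of genes in 5 classes of mean abundance, relative to the mean of the 8 libraries (vertical axis, log scale), against the total UMIs of each library (horizontal axis, log scale), with 1 point per library and class. The 5 genes with 3000 to 5000 UMIs stayed nearly level between 0.93 and 1.07, whereas the classes under 500 UMIs rose with the total.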

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

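All tests of explanations in this part were chosen after the results were seen. Of 20 sets of 4 libraries examined for a value far from the others, 2 stood out, where chance gives about 1 in 20. The total of trained replicate 1, 400934 UMIs, lay apart from the other 3 trained libraries (the gap was 0.883 of the range, above the limit of 0.829). The share of the 10 most abundant genes in untrained replicate 3, 13.1%, lay apart from the other 3 untrained libraries (0.838 of the range). These were the deepest trained and the shallowest untrained library.

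The first pattern is the ceiling of the counts just under 4096. Counts that are a fixed share of a library follow its total with a slope near 1, but the 5 genes above a mean of 3000 UMIs had a median slope of 0.0713, which is what saturation of a 6-base UMI predicts. A candidate explanation is therefore that most UMI sequences were used up for these genes, so that their counts understate their share in deep libraries. The UMI length is not given in the sources used here, and no biological explanation was tested.

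The second pattern is the separation of replicates 1 and 2 from replicates 3 and 4, with 484 genes, against 0 genes for training, which is balanced between the sets (415 genes passed with it as a term). The tables argue against depth as the whole cause, since 408 genes passed with the log2 library total as a covariate (367 of them among the 484). On counts corrected for the ceiling 494 genes passed (478 shared). The correction hardly changes low counts. Only 5, 9 and 55 genes had a mean of 3000 to 5000, 1500 to 3000 and 500 to 1500 UMIs. The count of genes could therefore hardly have fallen, and it does not test the ceiling as a cause in those abundant genes. The fold changes of replicates 3 and 4 against 1 and 2, computed apart in untrained and trained libraries, correlated at 0.569 across 4086 genes (0.25 and 0.21 for the other ways to part the numbers 2 against 2), and in each group taken alone this was the largest of the 3 ways (45.4% of their summed squared fold changes in untrained and 44.1% in trained libraries), which argues against chance differences in one group only, though the split was first seen over both groups. What stays open is whether the number marks a shared day, litter, level of dissection or library batch: same-numbered libraries deviated together, at a mean correlation of 0.377, but the labels name no batch, so these cannot be told apart.

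The third pattern is the pair of genes called with the replicate block. On corrected counts the blocked log2 fold change of ENSRNOG00000062158 was larger, 1.32 ± 0.25 (SE) against 1.14 ± 0.21. The correction raises the higher count of a pair more. Trained counts were higher in replicates 1 (2794 against 765 UMIs) and 3 (1882 against 780), which argues against the ceiling as the source there. Untrained counts were higher in replicates 2 (930 against 778 UMIs) and 4 (1524 against 898). There the ceiling could add to the trained excess, and by how much was not tested. Its edgeR adjusted p went from 0.0492 over 4086 genes to 0.128 over 4136 genes, as the unadjusted p rose from 2.41e-05 to 6.21e-05; why that p rose was not tested. The 8 ways to exchange trained and untrained within pairs are too few for a share under 0.05. The labelled way gave 2 genes, 5 of the 8 gave at least as many, and the highest other gave 9. A count of 2 genes thus did not set the real labels apart from exchanged ones. An effect of training on either gene remains a hypothesis.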

How the results depend on the processing

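Without the block, 0 genes passed under other scalings, DESeq2, both limma-voom fits, the robust fit, a threshold of 0.10, a filter of 5 CPM in 4 libraries (planned as stricter, but looser at this depth with 8258 genes), corrected counts and a filter of 20 UMIs (the last 2 chosen after seeing the data). With no filter 6 genes passed, ENSRNOG00000029042 and ENSRNOG00000062158 among them, and with the replicate block 2; leaving out 1 library gave 0 to 2 genes, the 2 without untrained replicate 2. The blocked count of 2 was kept under upper-quartile scaling, limma-voom and a threshold of 0.10. In alternatives combined with the block after seeing the data it was 1 with median-ratio scaling, 1 in the robust fit, 1 on corrected counts, 5 with 5 CPM in 4 libraries, 18 with no filter, 0 with 20 UMIs in 4 libraries and 0 with DESeq2, and 0 to 8 when both libraries of 1 number were left out (0 without replicate 1, 8 without replicate 3), where the filter was run anew; over the same 4086 genes it was 0, 2, 5 and 5 without replicates 1 to 4. The causes were not tested; the 20-UMI filter removed ENSRNOG00000029042 from the genes tested. The 4 printed genes kept their direction in every alternative in which they were tested; adjusted p of ENSRNOG00000062158 with the block ran from 4.09e-16 to 0.9998, and of ENSRNOG00000029042 from 1.16e-16 to 0.205 (0.264 without replicate 1 over the same 4086 genes). With the block that of ENSRNOG00000042905 ran from 0.000503 to 0.9998 and that of ENSRNOG00000052506 from 0.194 to 0.9998. The genes parting replicates 1 and 2 from 3 and 4 numbered 265 to 476 with 1 library left out (265 without trained replicate 4). Of the 35 splits of the 8 libraries into 4 and 4, all 35 gave at least the 0 genes of the real split, as any split must, so this count decides nothing; the highest other, 484, parts the libraries by number, which points to a structure of the samples. The tests of the 43 gene lists were not run, since no identifier had a symbol.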
